A study of Mus musculus with 6 samples.

How the data were processed

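RNA sequencing of 6 libraries of mouse CD4+ T cells was used, 3 unstimulated and 3 restimulated with antibodies against CD3 and CD28. The values are raw counts of reads per Ensembl gene, deposited by the authors as 1 table of 48440 genes with 1 column per library. Per the labels' protocols, RNA was extracted with a column kit and libraries were made with a TruSeq RNA preparation. Per the submitters' processing notes, STAR 2.5.2a, HTSeq, DESeq2 and the genome build GRCm38 were used, without a statement of which step each served. The annotation release, the strand setting and any read filter are not given in the sources used here. Reads of a gene and of an overlapping or antisense gene can therefore not be told apart, and genes with near-identical copies are uncertain.

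Group and replicate number were taken from the labels, which give no batch or date. They describe 3 replicates per group and do not say that these came from separate mice or cultures, nor that a number marks a shared mouse. The p-values thus measure only the spread between these libraries, which may be technical. No pair of libraries within a group agreed within counting noise: the dispersion index of pairs ran from 11.7 to 47.9, where counting noise alone gives about 1. Total counts ran from 29897720 to 30252923. The floor of 3 counts corresponded to 0.0992 to 0.1 CPM per library. Counting intervals (exact binomial, 95%) and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Of the 48440 genes, 26036 had no read in any library. Symbols, biotypes and GRCm38 coordinates came from GENCODE release M21, which matched 48058 identifiers and left 382 without a name.

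All tests started from the counts. edgeR 4.0.16 in R 4.3.3 was run with TMM normalization, filterByExpr on the group, robust dispersion estimates and the quasi-likelihood test with group as the only term, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The filter left 13314 genes, which held 99.9% of all counts. glmTreat tested changes against an absolute log2 fold change of 1. The SE of a log2 fold change was obtained from the change and the quasi-likelihood F statistic. CPM values were divided by TMM-scaled library sizes.

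Before the data were examined, 44 gene lists with 1059 entries were fixed, covering T cell activation, the ubiquitin system, growth and cell cycle, other cell types of spleen and lymph node, and mitochondrially encoded transcripts. All entries but 1, Ahsp, matched the table. Lists with at least 5 tested members, 37 in all, were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and adjusted over those lists. For each list the members that rose, fell or did not pass the test of single genes were counted, adjusted over all genes and adjusted over the list alone. Some genes stand in more than 1 list.

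The genes named were also fixed by a rule beforehand. It took the 8 largest rises and 8 largest falls among genes past the threshold with a mean of at least 1 CPM and no overlap between groups, leaving out predicted-gene names and receptor segments. It further took, for each list described, the 3 members with the smallest p that rose and the 3 that fell, or the most abundant member where none passed, and always Il2, Cd69, Egr2, Nr4a1, Ifng, Tnf, Myc, Cd4, Cd8a, Cd3e, Actb and Gapdh. Ighm was named in addition, after its level was seen, because it made up most of the B cell sum. Some genes that the rule took are not reported here.

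The alternatives were RLE normalization, library size alone, no filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, leaving out each library or replicate number in turn, library sizes without the 20 most abundant genes, an adjusted p of 0.01, camera with an estimated correlation, and fry. The pipeline was tested on simulated data of 13314 genes, with 200 genes changed. Each gene was drawn independently from its mean level over all 6 libraries, the library sizes and the trended dispersions. The changed genes were taken from those with a mean of at least 1 CPM, so changes at lower levels were not covered. The pipeline recovered 68% of the 100 genes changed by 1.5-fold and 89% of the 100 changed by 2-fold, and called 10 unchanged genes, 5.99% of its calls. In the data 77.5% of the tested genes were called. The adjusted threshold depends on the share of changed genes, so these rates do not give the recovery in the data. Normalization under so broad a change was not tested either. Camera called 0% of random simulated sets at p under 0.05. As the simulated genes were independent, this does not test the preset correlation. In the data the estimated correlation ran from -0.0125 to 0.974 over the lists. Tables were handled in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.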

Results

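RNA was measured in primary mouse CD4+ T cells, the helper lymphocytes that recognise antigen through the T cell receptor. The cells came from spleen and lymph node of wild-type mice. They had been activated for 3 days on antibodies against CD3 and CD28, which engage the receptor and its costimulatory partner, and expanded for 5 days with interleukin 2. They were then either kept at rest, the unstimulated group, or exposed again to both antibodies for 4 hours, the stimulated group, with 3 libraries in each. The libraries held between 29897720 and 30252923 counted reads, so that depth hardly differed between them, and a count of 3 reads corresponded to about 0.1 CPM in each. Levels are given as normalised read counts in CPM, mean ± SD over the 3 libraries of a group. Changes are log2 fold changes of stimulated over unstimulated cells with their SE.

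The series title frames the study around proteomics and ubiquitin marks that do not lead to degradation, and the RNA comparison asks which transcripts move when rested T cells meet the receptor stimulus again. Restimulation raised the early activation genes in all 3 stimulated libraries. The T cell growth factor Il2 went from 0.475 ± 0.117 to 251 ± 54.0 CPM (log2 fold change 9.04, SE 0.24), and the activation marker Cd69 from 11.3 ± 1.93 to 422 ± 22.7 CPM (log2 fold change 5.22, SE 0.13). The receptor-induced transcription factors Egr2 and Nr4a1 rose 90.3-fold and 42.3-fold, Egr2 from 2.38 ± 1.497 to 215 ± 11.9 CPM and Nr4a1 from 3.97 ± 1.53 to 168 ± 12.3 CPM. Without unstimulated replicate 1 the rise of Egr2 was 142-fold. The cytokines Ifng and Tnf rose from 0.316 ± 0.115 to 67.8 ± 9.68 CPM and from 4.87 ± 0.343 to 346 ± 39.3 CPM, and the growth regulator Myc from 167 ± 25.5 to 1340.4 ± 23.5 CPM. The coreceptor transcript Cd4 was abundant in both groups and fell from 984 ± 40.2 to 333 ± 16.7 CPM (log2 fold change -1.56, SE 0.063), as did the receptor subunit Cd3e (from 238 ± 15.4 to 99.3 ± 3.46 CPM). Cd8a, which marks cytotoxic T cells, stayed low at 3.83 ± 0.328 and 8.22 ± 0.424 CPM, a rise of 1.10 on the log2 scale. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the adjusted p of these 10 genes lay between 4.1e-09 and 5.3e-05.

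Among the 2 housekeeping genes, Actb was 3806 ± 198 and 4197 ± 207 CPM (log2 fold change 0.14, SE 0.056; edgeR, adjusted p = 0.0444). Its call was lost with library size alone, where the change was 0.00047 (adjusted p = 0.994), with no filter (adjusted p = 0.0754), with a filter of 1 CPM (adjusted p = 0.0649) and on leaving out stimulated replicate 1 (adjusted p = 0.113), stimulated replicate 2 (adjusted p = 0.0513), unstimulated replicate 1 (adjusted p = 0.109) or unstimulated replicate 2 (adjusted p = 0.149) (range of 0.0174 to 0.994 over its alternatives). Gapdh differed by -0.10 (SE 0.057, edgeR, adjusted p = 0.137), and by -0.24 with library size alone, where it passed the test (adjusted p = 0.0051; range of 0.0051 to 0.604 over its alternatives).

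**Figure D1:**
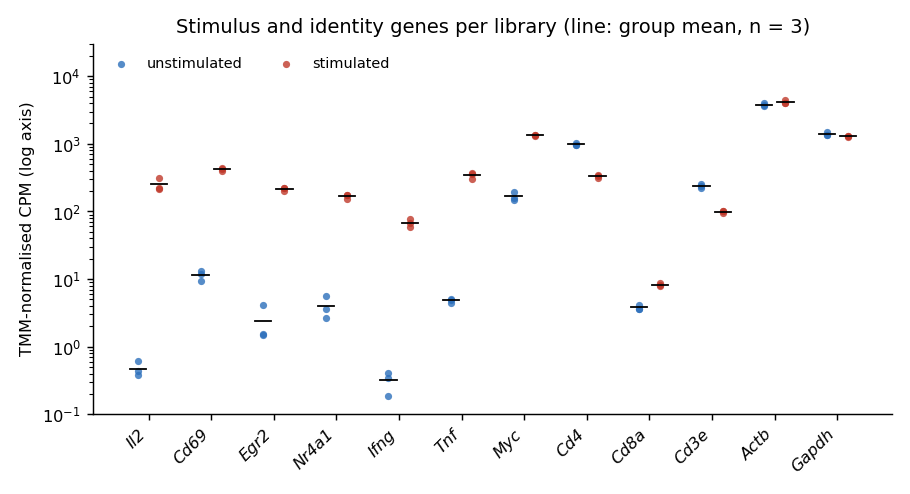
Level of the 12 stimulus and identity genes in each library (TMM-normalised CPM, log axis), unstimulated in blue and stimulated in red, 3 points per group with a line at the mean. Il2, Cd69, Egr2, Nr4a1, Ifng, Tnf, Myc and Cd8a lie higher in all stimulated libraries, Cd4 and Cd3e lower, while Actb and Gapdh differ little.

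The stimulus moved most of the transcriptome. Of 13314 tested genes, 5113 rose, 5207 fell and 2994 did not pass edgeR's quasi-likelihood test at an adjusted p of 0.05. Changes of more than 2-fold, tested against that size with glmTreat, numbered 2313 up and 2428 down. The groups of 3 libraries did not overlap for 10627 genes, or 79.8%, where chance gives 10%. The first principal component held 92.0% of the variance. The median change over all genes was -0.043, and scaling by library size alone moved it by -0.14, so that changes near that size depend on the scaling. RNA content per cell was not measured, so all changes are relative to the other transcripts of the library.

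**Figure D2:**
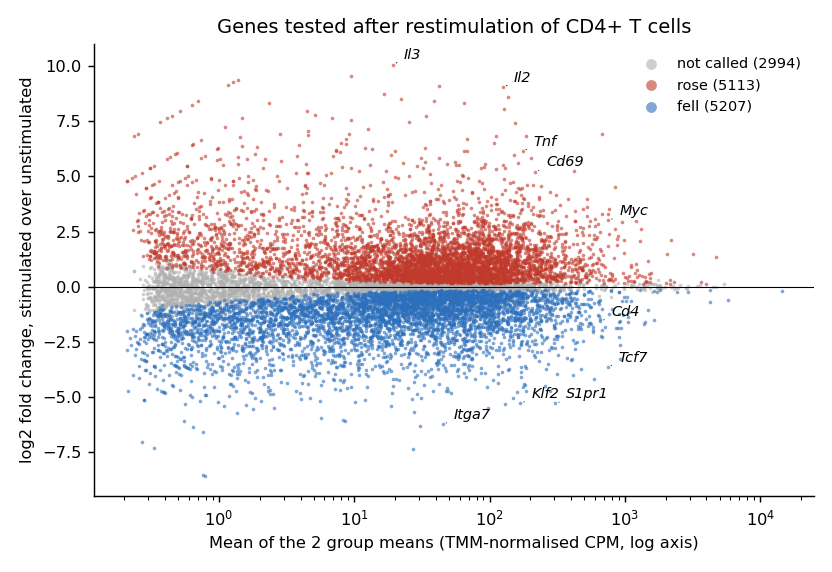
Change of each tested gene (log2 fold change, stimulated over unstimulated) against the mean of both group means in TMM-normalised CPM (log axis). Points are coloured by the edgeR call, 5113 that rose, 5207 that fell and 2994 not called, with 10 genes named in the text labelled.

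Among the 8 largest rises, Il3, a haematopoietic cytokine (ENSMUSG00000018914, chromosome 11, 54265303 to 54267277 in GRCm38), had 3 reads over the 3 unstimulated libraries and 3298 over the stimulated ones, a ratio of 1217 (95% counting interval 416 to 5904). All 3 resting reads lay in unstimulated replicate 1. Without it the resting count was 0, and Il3 was at least 814-fold higher against a floor of 3 counts, while without unstimulated replicate 2 or 3 the ratio was 811 or 809. Plagl1, a zinc finger transcription factor (ENSMUSG00000019817, chromosome 10, 13060504 to 13131694), had 2 and 1627 reads, a ratio of 900.5 (249 to 7442), which was 598 (165 to 4946) without unstimulated replicate 3. The transcription factor Egr4 and the cytokines Il31 and Il17a had 0 reads in all unstimulated libraries. Against a floor of 3 counts over that group, Egr4 was at least 87.8-fold higher after stimulation, Il31 at least 80.4-fold and Il17a at least 74.2-fold. The chemokine Ccl1 rose from 0.148 ± 0.132 to 84.1 ± 17.7 CPM, on 14 resting reads, a ratio of 571 (339.8 to 1044) that was 890.3 without unstimulated replicate 1 and 380.3 without unstimulated replicate 2. The chromatin-associated factor Utf1 rose from 0.0737 ± 0.102 to 33.1 ± 14.4 CPM, on 7 resting reads, a ratio of 448 (217 to 1116). Most of those reads lay in unstimulated replicate 2, without which 1 read was left and the ratio was 2092 (375 to 82677). Il2 (ENSMUSG00000027720, chromosome 3, 37120523 to 37125959) rose 525-fold.

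The deepest falls included Rap1gap2, which switches off the small GTPase Rap1, from 59.9 ± 9.32 to 0.748 ± 0.152 CPM (log2 fold change -6.32, SE 0.18; ENSMUSG00000038807, chromosome 11, 74383356 to 74610915). The integrin chain Itga7 fell from 88.7 ± 5.04 to 1.18 ± 0.162 CPM (log2 fold change -6.23, SE 0.11; ENSMUSG00000025348, chromosome 10, 128933818 to 128958282). The orphan receptor Gprc5b, the RING-type ubiquitin ligase Rnf144a and the cohesin subunit Rec8 fell 67.8-fold, 51.2-fold and 45.9-fold, Rnf144a from 53.9 ± 4.93 to 1.05 ± 0.407 CPM. Without unstimulated replicate 3 the fall of Rec8 was 30.4-fold. The adjusted p of these genes and of the 8 with the largest rises lay between 3.5e-09 and 0.00021 in edgeR's quasi-likelihood test. The other 3 of the 8 deepest falls were processed pseudogenes, Gmfg-ps (-7.36), Bambi-ps1 (-6.03) and Hmgb1-ps8 (-5.96), whose reads can be shared with their parent genes and are uncertain. The call of Gmfg-ps was lost with limma-voom (adjusted p = 0.25) and on leaving out stimulated replicate 1 (adjusted p = 0.0767), stimulated replicate 2 (adjusted p = 0.0518) or unstimulated replicate 3 (adjusted p = 0.0501) (range of 6.6e-13 to 0.25 over its alternatives).

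Secreted signals rose together. All but 1 of the 29 tested cytokines rose, with a median change of 4.78 (camera, adjusted p = 5.9e-12, and adjusted p = 0.122 with an estimated correlation). The lymphotoxin gene Lta went from 14.7 ± 0.435 to 364 ± 8.82 CPM, and Tnfsf11, which encodes RANKL, from 4.77 ± 0.390 to 295 ± 28.0 CPM. The exception was Il16, which fell from 231 ± 6.41 to 50.2 ± 0.591 CPM (log2 fold change -2.20, SE 0.063). All 12 tested chemokines rose, with a median of 5.44, or 5.52 with the 2 members of 3 or fewer reads at rest set to their counted ratio or bound (camera, adjusted p = 9.3e-07, and adjusted p = 0.122 with an estimated correlation). Ccl4 rose 318-fold (from 0.401 ± 0.0684 to 128 ± 24.8 CPM), Cxcl10 346-fold (from 0.221 ± 0.109 to 77.9 ± 19.8 CPM) and Ccl3 69.1-fold (from 0.221 ± 0.144 to 15.6 ± 0.477 CPM).

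Of 19 activation and costimulatory receptors, 14 rose and 5 fell (camera, adjusted p = 8.5e-06, and adjusted p = 0.122 with an estimated correlation). The TNF-receptor family members Tnfrsf4 (OX40) and Tnfrsf9 (4-1BB) rose from 71.0 ± 2.29 to 1621 ± 154 CPM and from 6.56 ± 0.903 to 316 ± 18.4 CPM. Among the members that fell, Cd27 went from 299 ± 23.9 to 90.8 ± 3.86 CPM and Cd28 from 452 ± 55.0 to 160.0 ± 12.9 CPM. Inhibitory receptors and ligands divided 7 up, 4 down and 1 not called (camera, adjusted p = 0.505). Havcr2, which encodes TIM-3, rose 119.7-fold, Pdcd1 (PD-1) 15.9-fold and Cd274 (PD-L1) 21.8-fold, whereas Ctla4 fell from 207 ± 4.47 to 81.1 ± 4.64 CPM and Vsir from 355 ± 13.4 to 182 ± 14.2 CPM.

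Immediate early and early response genes rose in 25 of 29 cases and fell in 1 (camera, adjusted p = 4.4e-10, and adjusted p = 0.158 with an estimated correlation). The MAP kinase phosphatases Dusp2 and Dusp5 rose 5.84-fold and 10.05-fold and the signalling inhibitor Spry1 27.3-fold, while Klf6 fell by 0.39 (SE 0.096). The call of Klf6 was lost without both libraries of replicate 2 (adjusted p = 0.0954), with a range of 0.00075 to 0.0954 over its alternatives. Of the 24 NF-kB family members and targets 23 rose and 1 fell, with a median of 1.91 (camera, adjusted p = 1.6e-11, and adjusted p = 0.122 with an estimated correlation). The survival gene Bcl2l1 went from 27.4 ± 0.886 to 534 ± 7.60 CPM (log2 fold change 4.28, SE 0.068). Its relatives Bcl2a1b and Bcl2a1d rose 19.5-fold and 19.4-fold, but are near-identical copies whose reads cannot be assigned with certainty.

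Helper lineage regulators numbered 22 up, 6 down and 6 not called of 34 (camera, adjusted p = 0.19). Irf8 rose from 21.6 ± 4.39 to 814 ± 124 CPM and Tbx21, which encodes T-bet, from 52.6 ± 6.27 to 299 ± 20.3 CPM, while Stat4 fell from 188 ± 15.1 to 20.5 ± 1.85 CPM. Among 8 suppressors of cytokine signalling 6 rose and 1 fell (camera, adjusted p = 0.181), with Cish and Socs1 up 9.20-fold and 6.97-fold and Socs3 down by 0.48 (SE 0.12). Without unstimulated replicate 1, camera called both the lineage and the suppressor list (adjusted p = 0.0197 for each; range of 0.0197 to 0.748 over the camera alternatives for the first and 0.0197 to 0.67 for the second). Of 10 cytotoxic molecules 5 rose, 1 fell and 4 did not pass (camera, adjusted p = 0.365). Granzyme B, from Gzmb, rose from 135 ± 48.5 to 853 ± 189.5 CPM and the granule proteoglycan Srgn from 484 ± 36.8 to 1176 ± 43.5 CPM, and Lamp1 fell from 256 ± 1.71 to 171 ± 6.35 CPM.

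Genes of resting and recirculating T cells fell. Of 30 quiescence and lymphocyte trafficking genes 24 fell and 4 rose, with a median of -2.21 (camera, adjusted p = 2.2e-13, and adjusted p = 0.141 with an estimated correlation). The transcription factor Klf2 fell 39.0-fold (from 329 ± 15.3 to 8.43 ± 0.378 CPM) and S1pr1, the receptor for exit from lymphoid organs, 39.0-fold (from 597 ± 29.96 to 15.3 ± 1.84 CPM). Tcf7, which encodes TCF1, fell from 1379 ± 90.1 to 111 ± 4.41 CPM. Slfn2 and Tob2 rose by 1.61 and 0.72. T cell receptor complex and proximal signalling genes fell in 20 of 30 cases and rose in 6, or 7 adjusted over the list alone (camera, adjusted p = 0.0065, and adjusted p = 0.308 with an estimated correlation). The lipid kinase Dgka fell 13.4-fold (from 874 ± 41.2 to 65.0 ± 2.37 CPM) and Plcg1 2.80-fold, and the kinase Zap70 and the adaptor Lcp2 rose by 1.00 and 1.33. In the same libraries the summed B cell markers were lower after stimulation (from 2081 ± 739.9 to 1009 ± 273 CPM). That sum was nearly all Ighm (1985 and 963 CPM).

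Apoptosis regulators moved both ways, 15 up and 7 down of 26 (camera, adjusted p = 0.142). Besides Bcl2l1, Bid and Cycs (cytochrome c) rose 5.52-fold and 4.85-fold, and the death-promoting BH3 genes Bmf and Bbc3 fell 9.88-fold and 7.34-fold.

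The ubiquitin system was examined part by part. Transcripts of the proteasome, which degrades ubiquitylated proteins, rose as a set. Of the 14 genes of the 20S core 13 rose and none fell, with a median of 1.02 (camera, adjusted p = 0.0019, and adjusted p = 0.64 with an estimated correlation). Of the 22 genes of the 19S regulator 20 rose and 1 fell, with a median of 0.87 (camera, adjusted p = 0.00023, and adjusted p = 0.422 with an estimated correlation). Psma7 rose from 114 ± 10.5 to 381 ± 9.44 CPM, Psma4 from 121 ± 4.02 to 315 ± 3.35 CPM and Psmd7 from 54.8 ± 2.36 to 211 ± 1.73 CPM, and Psmd10, an assembly chaperone, fell by 0.39 (SE 0.076). With library size alone, 12 of the 20S genes rose and 1 fell. Immunoproteasome and antigen processing genes counted 12 up and 1 down of 14, against 8 up and 1 down with library size alone, without passing camera (adjusted p = 0.0598). The activator subunits Psme3, Psme2 and Psme1 rose 5.24-fold, 2.47-fold and 2.07-fold. H2-D1 fell by 0.22 (SE 0.065), a call lost on leaving out stimulated replicate 2 (adjusted p = 0.0563) with a range of 0.00058 to 0.0717 over its alternatives, and its reads can be shared with other class I genes. Camera called this list without unstimulated replicate 1 (adjusted p = 0.032) or stimulated replicate 2 (adjusted p = 0.0221), and with replicate number as a block (adjusted p = 0.0314; range of 0.0221 to 0.67 over the camera alternatives).

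For the enzymes that attach and remove ubiquitin, camera called none of the lists against other genes. Of 33 E2 conjugating enzymes 21 rose and 7 fell (camera, adjusted p = 0.19). Ube2h fell 22.1-fold (from 346 ± 27.5 to 15.7 ± 0.342 CPM; log2 fold change -4.47, SE 0.087) and Ube2b 3.29-fold (from 169.6 ± 11.8 to 51.6 ± 2.88 CPM), while Cdc34 and Ube2q2 rose 3.27-fold and 3.09-fold. Of 20 ubiquitin, ubiquitin-like and E1 genes 13 rose and none fell, against 8 up and 4 down with library size alone (camera, adjusted p = 0.19). Isg15, an interferon-induced ubiquitin-like modifier, rose from 3.29 ± 0.645 to 370.1 ± 121 CPM and Sumo2 1.77-fold. E3 ligases with roles in T cells divided 24 up, 19 down and 13 not called of 56, against 23 up and 22 down with library size alone (camera, adjusted p = 0.681). Asb2 rose from 22.4 ± 4.14 to 118 ± 4.42 CPM and Siah2 from 8.85 ± 0.879 to 31.9 ± 0.745 CPM. Rnf125 and Rnf167 fell from 31.2 ± 7.62 to 2.95 ± 0.314 CPM and from 135 ± 11.6 to 31.1 ± 0.488 CPM.

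Cullin-RING ligase components were 26 up and 19 down of 52, or 20 down adjusted over the list alone, against 24 up and 21 down with library size alone (camera, adjusted p = 0.346). The COP9 signalosome subunits Gps1 and Cops7a rose 5.03-fold and 3.96-fold. Klhl6, which also stands in the list of T cell E3 ligases, fell 23.6-fold (from 340.0 ± 16.5 to 14.4 ± 2.74 CPM; log2 fold change -4.56, SE 0.14). NEDD4-family ligases and their adaptors fell in 11 of 14 cases and rose in 2 (camera, adjusted p = 0.143). The arrestin-domain gene Txnip fell from 777 ± 37.3 to 48.8 ± 9.49 CPM and Arrdc1 from 97.2 ± 3.01 to 31.4 ± 1.53 CPM, whereas the adaptors Ndfip1 and Ndfip2 rose by 1.00 and 0.71.

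For chains that signal without degradation, the linear and K63 machinery counted 13 up and 9 down of 28, against 9 up and 11 down with library size alone (camera, adjusted p = 0.681). Ube2n and Ube2v2, which together build K63-linked chains, rose 2.26-fold (from 59.2 ± 6.04 to 134 ± 5.69 CPM) and 2.32-fold (from 8.43 ± 0.194 to 19.6 ± 0.0581 CPM). The kinase subunits of this list went both ways. Chuk rose by 0.75 (SE 0.065), whereas Ikbkb and Ikbkg and the deubiquitylase Cyld fell by 0.85, 0.63 and 0.93. Of 71 deubiquitylases 36 rose and 22 fell, against 30 up and 27 down with library size alone (camera, adjusted p = 0.167). Usp36 and Usp10 rose 6.26-fold and 5.11-fold, Usp36 from 45.5 ± 4.31 to 285 ± 12.3 CPM, and Mindy2 and Usp3 fell 8.67-fold and 4.18-fold, Mindy2 from 107 ± 17.1 to 12.4 ± 1.48 CPM. Ubiquitin shuttles and receptors were 11 up and 8 down of 23, with a median of 0.088 that turned to -0.052 with library size alone (camera, adjusted p = 0.57). Ubqln4 rose 4.43-fold and Rad23b 2.54-fold, and the autophagy receptor Nbr1 fell from 103 ± 3.11 to 25.8 ± 0.854 CPM.

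**Figure D3:**
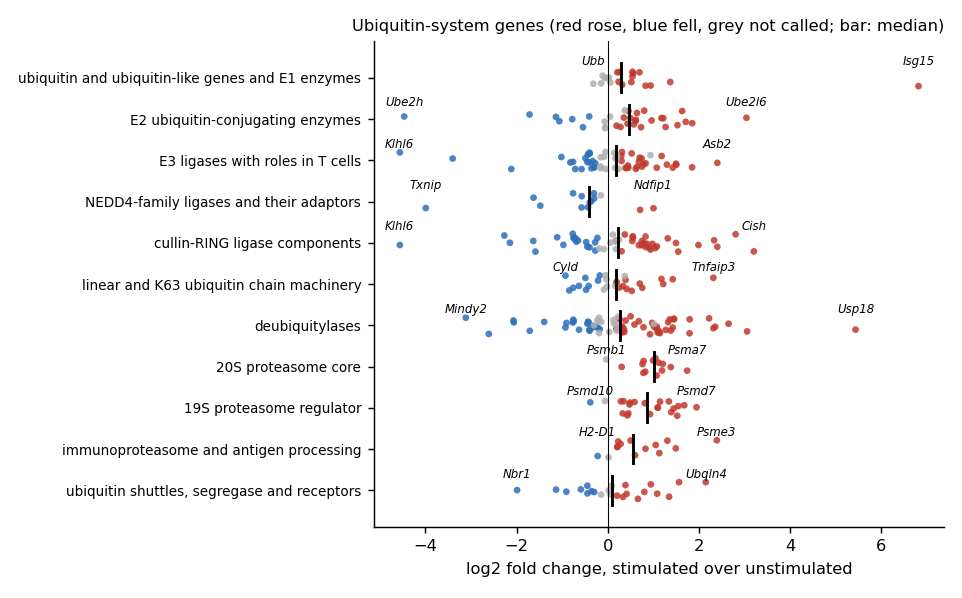
Change of each tested gene of the 11 ubiquitin-system lists (log2 fold change, stimulated over unstimulated), red where it rose, blue where it fell and grey where edgeR did not call it, with a bar at the list median and the extreme members named. The medians of the 20S core (1.02) and 19S regulator (0.87) lie farthest to the right, while ligase and deubiquitylase lists spread to both sides. With library size alone the median of the shuttles lies at -0.052.

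Genes for building ribosomes rose throughout. All 41 ribosome biogenesis genes rose, 40 of them by more than 2-fold, with a median of 2.96 (camera, adjusted p = 3.6e-38, and adjusted p = 0.144 with an estimated correlation). The assembly factors Ppan and Mrto4 went from 26.0 ± 2.15 to 435 ± 4.42 CPM and from 17.5 ± 0.909 to 264 ± 11.0 CPM, and Bysl from 14.9 ± 0.987 to 164 ± 4.51 CPM. The 56 cytosolic ribosomal protein genes hardly moved, with 16 up, 4 down and 36 not called, or 14 up and 3 down adjusted over the list alone (camera, adjusted p = 0.799). Their median of 0.059 turned to -0.081 with library size alone, where 2 rose and 21 fell. Rps2 rose by 0.39 (SE 0.060) and Rpl3 fell by 0.22 (SE 0.042). These genes have many processed pseudogenes that can take their reads.

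Amino acid transport and tRNA synthetase genes rose in 29 of 32 cases and fell in 2 (camera, adjusted p = 5.9e-12, and adjusted p = 0.145 with an estimated correlation). The glutamine carrier Slc1a5 rose from 216 ± 4.18 to 1028 ± 37.0 CPM, the serine pathway enzyme Shmt2 from 53.7 ± 1.93 to 338 ± 3.85 CPM and asparagine synthetase Asns from 6.15 ± 0.972 to 103 ± 1.25 CPM, and Qars and Slc38a2 fell by 0.82 and 0.35. The call of Slc38a2 was lost without both libraries of replicate 2 (adjusted p = 0.0519), with a range of 0.00016 to 0.0519 over its alternatives. Of 24 heat shock and chaperone genes 21 rose and 2 fell (camera, adjusted p = 8.3e-09, and adjusted p = 0.308 with an estimated correlation). The mitochondrial chaperones Hspd1 and Hspa9 rose from 125 ± 11.1 to 1236 ± 62.5 CPM and from 126 ± 10.4 to 984 ± 59.3 CPM, and Cct3, of the cytosolic chaperonin, 5.15-fold. Dnajb4 fell 3.85-fold, and Dnajb1 by 0.22, a call lost with DESeq2's test (adjusted p = 0.0725), with RLE normalization (adjusted p = 0.0605) and on leaving out stimulated replicate 2 (adjusted p = 0.149), stimulated replicate 3 (adjusted p = 0.123), unstimulated replicate 1 (adjusted p = 0.0925) or unstimulated replicate 2 (adjusted p = 0.0632) (range of 0.0019 to 0.217 over its alternatives).

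Cholesterol synthesis and uptake genes rose in 13 of 22 cases, or 14 adjusted over the list alone, and fell in 5 (camera, adjusted p = 0.033, and adjusted p = 0.67 with an estimated correlation). The call was also lost with a filter of 1 CPM (adjusted p = 0.055), with replicate number as a block (adjusted p = 0.0584) and without stimulated replicate 3 (adjusted p = 0.0613; range of 0.0118 to 0.67 over the camera alternatives). Cyp51 rose from 109 ± 2.96 to 337 ± 17.7 CPM, while Mvk fell from 28.5 ± 2.25 to 10.4 ± 1.68 CPM. Glycolysis genes divided 12 up and 7 down of 22, against 11 up and 9 down with library size alone (camera, adjusted p = 0.57). The lactate carrier Slc16a1 rose 11.2-fold (from 33.4 ± 2.46 to 373 ± 29.4 CPM) and Ldha 2.27-fold, and Pdk1 and Aldoc fell 4.54-fold and 3.53-fold.

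All 30 tested G2 and mitosis genes fell, 25 of them by more than 2-fold, with a median of -1.81 (camera, adjusted p = 1e-15, and adjusted p = 0.247 with an estimated correlation). The spindle gene Nusap1 fell from 343 ± 22.9 to 26.4 ± 1.14 CPM (log2 fold change -3.70, SE 0.081), Dlgap5 from 141 ± 10.3 to 30.02 ± 0.770 CPM and Top2a from 1464 ± 96.2 to 396 ± 14.5 CPM. In the same libraries the summed markers of B cells went from 2081 ± 739.9 to 1009 ± 273 CPM, of NK cells from 5.83 ± 0.232 to 1.45 ± 0.219 CPM and of gamma-delta T cells from 12.4 ± 4.08 to 7.21 ± 2.31 CPM. The B cell sum was nearly all Ighm (1985 and 963 CPM) and the NK cell sum at rest mostly Fcgr3 (4.54 CPM). Cd79a, the next highest B cell marker of the list, stood at 21.7 CPM at rest, far under Top2a. Outside the list Igkc stood at 522 CPM and Jchain at 219.5 CPM at rest, so Cd79a alone does not bound the B-lineage RNA. Of 30 DNA replication and S phase genes 10 rose, 13 fell and 7 did not pass, against 8 up and 17 down with library size alone (camera, adjusted p = 0.791). The licensing genes Mcm2 and Orc1 rose from 94.8 ± 8.49 to 291 ± 27.1 CPM and from 8.48 ± 0.569 to 31.4 ± 4.14 CPM, and the nucleotide synthesis genes Rrm2 and Tyms fell from 259 ± 18.5 to 59.1 ± 2.55 CPM and from 53.9 ± 5.07 to 22.3 ± 1.59 CPM.

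Interferon-stimulated genes rose in 31 of 32 cases and none fell, with a median of 2.66 (camera, adjusted p = 9.3e-07, and adjusted p = 0.64 with an estimated correlation). Oas2 went from 1.34 ± 0.270 to 40.9 ± 9.08 CPM, Oasl2 from 1.54 ± 0.0682 to 49.3 ± 14.8 CPM and the exonuclease Isg20 from 18.0 ± 0.919 to 205 ± 46.9 CPM. Summed macrophage markers were higher in the same libraries (from 107 ± 6.19 to 187 ± 33.1 CPM). The gain lay in Ctss and Mpeg1, while Itgam and Adgre1 fell, from 3.33 to 0.69 CPM and from 2.05 to 0.734 CPM. Autophagy and lysosome genes fell in 23 of 33 cases and rose in 7 (camera, adjusted p = 0.00016, and adjusted p = 0.122 with an estimated correlation). The lysosomal protease Ctsd fell 7.38-fold (from 222 ± 17.2 to 30.1 ± 1.92 CPM) and the autophagy kinase Ulk1 4.81-fold (from 80.0 ± 2.88 to 16.6 ± 0.622 CPM), while Atg16l1 and Gabarapl1 rose by 0.97 and 0.94. As beside the falling T cell receptor list, the summed B cell markers, nearly all Ighm, were lower in these stimulated libraries, at 1009 ± 273 CPM.

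**Figure D4:**
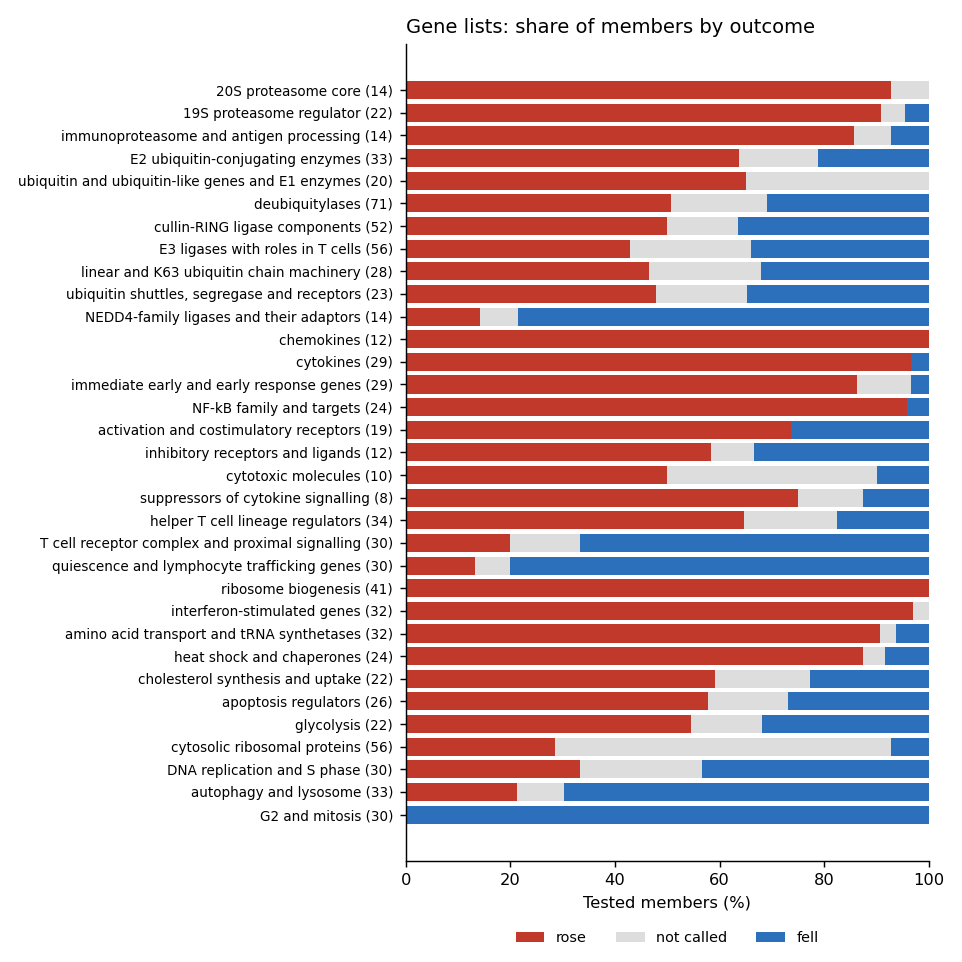
Share of the tested members (%) of each tissue, ubiquitin-system and growth list that rose (red), fell (blue) or were not called (grey) in edgeR's test, with the number tested in brackets. All 41 ribosome biogenesis genes and 12 chemokines rose and all 30 G2 and mitosis genes fell. With library size alone the balance of cytosolic ribosomal proteins turned to 2 up and 21 down, and that of the linear and K63 machinery to 9 up and 11 down.

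By camera with a preset correlation of 0.01, 12 of the 37 lists tested rose and 4 fell. With an estimated correlation camera called 0 lists, and 9 had an unadjusted p under 0.05. Fry, which tests each list by itself, found 25 lists moving up on balance and 6 down, and 36 with change in either direction. Adjusted over the list alone, 38 of 43 lists kept their counts of rising and falling members, and the counts of the other 5 are given at those lists.

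Markers of other cells of spleen and lymph node were summed per library. Of 13 B cell markers 9 fell and 1, Fcer2a, rose (camera, adjusted p = 0.168), and their summed level was nearly all Ighm, at 1985 ± 739 and 963 ± 277 CPM. Cd79b and Ms4a1 fell from 16.1 ± 1.14 to 2.82 ± 0.329 CPM and from 12.3 ± 1.93 to 3.94 ± 0.584 CPM. Summed CD8 T cell markers were 22.4 ± 2.12 and 22.9 ± 2.63 CPM, with 1 of 2 up and 1 down. The latter, Cd8b1, lost its call with DESeq2's test (adjusted p = 0.0513). In edgeR it was lost without both libraries of replicate 2 (adjusted p = 0.3) or replicate 3 (adjusted p = 0.0834), and without some single libraries, given below. Summed gamma-delta T cell markers went from 12.4 ± 4.08 to 7.21 ± 2.31 CPM, with 1 of 4 tested members falling. This was Trdc, whose call was lost without both libraries of replicate 2 (edgeR, adjusted p = 0.0615). NK cell markers went from 5.83 ± 0.232 to 1.45 ± 0.219 CPM, with 1 of 2 tested members falling. That member, Fcgr3, made up most of the sum at rest and fell from 4.54 ± 0.417 to 0.175 ± 0.153 CPM, 25.4-fold or 49.4-fold without stimulated replicate 2. Macrophage markers had 2 up and 2 down of 6 tested (camera, adjusted p = 0.919), with a median of -0.37 but a mean of 0.050 and an upward camera direction, Ctss rising from 97.4 ± 7.10 to 149 ± 19.2 CPM and Mpeg1 from 1.88 ± 0.264 to 33.8 ± 13.8 CPM. Dendritic cell markers had 5 up and 4 down of 9 (camera, adjusted p = 0.887) and summed to 229.9 ± 2.24 and 252 ± 23.9 CPM, with Cd74 rising from 111 ± 10.1 to 149.5 ± 11.9 CPM.

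Neutrophil markers, none of them abundant enough to test, summed to 2.40 ± 3.32 and 0.292 ± 0.142 CPM. The unstimulated mean rested on replicate 2, at 6.23 CPM, and was 0.489 CPM without it. Erythroid and platelet markers summed to 3.16 ± 1.11 and 1.96 ± 0.332 CPM, with 1 of 2 tested falling, or 0 adjusted over the list alone. Mast cell and basophil markers summed to 1.33 ± 0.251 and 1.92 ± 0.378 CPM, with 1 of 2 rising and 1 falling. Stromal and endothelial markers went from 188 ± 9.62 to 53.4 ± 6.94 CPM, with 1 of 4 tested rising and 1 falling, the latter Pecam1, which T cells also express (from 186 ± 10.3 to 49.9 ± 5.99 CPM). Mitochondrially encoded transcripts, a sign of RNA quality, summed to 9561 ± 1520.1 and 11423 ± 1660.1 CPM, with 3 of 7 tested rising (camera, adjusted p = 0.669). Over the unstimulated libraries mt-Co2, mt-Co3 and mt-Atp6 had 4, 17 and 11 reads, against 492101 for mt-Co1. They thus hardly enter the sum, for a reason that was not tested, and the sum is only a limited sign of RNA quality.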

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

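The alternatives were chosen before the data were examined. The number of changed genes, 10320, ranged from 8858 without replicate 2 to 10436 without unstimulated replicate 1, with 4391 to 5179 up and 4467 to 5257 down. Beyond 2-fold the range was 3954 to 4845, with 1966 to 2390 up and 1988 to 2455 down. Under the other settings the count ran from 9168 (adjusted p under 0.01) to 10842 (replicate block), and beyond 2-fold from 3880 (DESeq2) to 4974 (replicate block). No call reversed: library size alone kept 9770 of the 10320 calls in direction, changed the sign of 2 without calling them, and gave 44.0% rising among changed genes against 49.5%. DESeq2 kept 10060 and limma-voom 10268.

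The lists changed by camera numbered 16, and 15 to 19 with single libraries left out (11 to 15 up, 4 down). With an estimated correlation camera called 0 lists, 0 up and 0 down, and fry called 31, of which 25 up. Fry does not set a list against other genes. Both camera runs differ only in the correlation setting. The estimate was 0.507 for ribosome biogenesis, 0.776 for the 20S core and 0.758 for interferon-stimulated genes, far above the preset of 0.01. For autophagy and lysosome genes it was 0.0084, and that call was lost too, so a higher correlation is not the whole difference. What else contributed was not tested.

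Of 209 named genes 192 kept their call under every alternative run, and 17 did not under at least 1. Single libraries decided 10 of these. Besides Actb, Gmfg-ps, H2-D1 and Dnajb1, given with the results, Cd8b1 lost its call without stimulated replicate 2 (adjusted p = 0.113), stimulated replicate 3 (adjusted p = 0.131) or unstimulated replicate 2 (adjusted p = 0.136), mt-Nd5 without stimulated replicate 2 (adjusted p = 0.069), stimulated replicate 3 (adjusted p = 0.0786), unstimulated replicate 1 (adjusted p = 0.0518) or unstimulated replicate 2 (adjusted p = 0.0656), and Rplp0 without stimulated replicate 2 (adjusted p = 0.0552) or stimulated replicate 3 (adjusted p = 0.0552). Hba-a1, Kit and Col1a1 lost theirs without 4, 2 and 2 of the 6 libraries, with an adjusted p of up to 0.146, 0.1 and 0.135 over all alternatives.

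Both groups carry replicate numbers 1 to 3, which the labels do not tie to a mouse. The deviations of same-numbered libraries from their group means correlated across genes at 0.36, 0.084 and 0.38, so by this check across all genes not every pair passed 0.1, and the numbers were not taken to pair the samples. The use of immunoglobulin V genes, examined later and given with the other observations, did pass 0.1 in all 3 pairs (0.371 to 0.542), so a source shared by number stays open. The second principal component, with 3.68% of the variance, separated the numbers alike in both groups, at 25.7 and 18.5 for number 1, 1.02 and -2.23 for number 2 and -24.6 and -18.4 for number 3 (unstimulated and stimulated). Each library did correlate best with its own number, all other pairs lying at or below -0.012, a hint from the data and not the design. Deviations from a group mean cancel out, so positive values for same numbers push those of the other pairs down. The negative values are thus no separate evidence. With replicate number as a block, 10842 genes changed (5326 up, 5516 down), 4974 by more than 2-fold (2412 up, 2562 down) and 16 lists (12 up, 4 down), and 10292 of the 10320 calls were kept. Depth limits the low end: genes under about 0.1 CPM lie at the 3-count floor. Simulated changes of 1.5-fold, in genes of at least 1 CPM, were recovered in 68% of cases. The simulation kept the depth and library number of these data, so it does not tell what limits recovery. It changed 200 of 13314 genes, far fewer than were called in the data, so this rate does not carry over to them.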

Other observations

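All tests in this part, and the genes named as examples, were chosen after the results were seen. Protein-coding genes were grouped by the letters their symbols share, and the balance of rising and falling members was compared with all other called genes in 100 families of at least 12 tested members (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted over families; genes of a family are not independent). By this test 12 families leaned up and 11 down. Of 29 small-subunit genes of the mitochondrial ribosome (Mrps) 26 rose and 1 fell (adjusted p = 4.1e-05), as did 37 of 49 large-subunit genes (Mrpl, 6 fell, adjusted p = 7.9e-05), such as Mrpl12 with 47.7 and 231 CPM. Of 14 mitochondrial import genes (Timm) 12 rose and 0 fell, with Timm10 at 5.52 and 63.7 CPM. RNA polymerase subunits (Polr, 23 of 28 up, adjusted p = 0.0012) included the polymerase III gene Polr3d at 5.79 and 84.7 CPM. Translation factors (Eif, 41 of 53 up) included Eif5a at 367 and 2259 CPM, and 18 of 20 nucleoporins (Nup) rose.

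Among the families that leaned down, kinesins (Kif) fell in 23 of 28 cases and rose in 3 (adjusted p = 0.00087), centrosomal genes (Cep) in 23 of 33. Intraflagellar transport genes (Ift), better known from cilia, which T cells lack, fell in 12 of 14 cases (median -1.68, adjusted p = 0.0122), with Ift80 at 75.9 and 9.19 CPM. Rab GTPase-activating genes (Tbc) fell in 21 of 29 cases. Among ubiquitin ligase subunits the F-box genes (Fbxo) fell in 19 of 29 cases and rose in 5 (adjusted p = 0.0225), while Rnf genes (21 up, 29 down of 66, adjusted p = 0.527) and Trim genes (17 up, 17 down of 42, adjusted p = 1) showed no such lean in this test. With library size alone the medians of the leaning families named here kept their sign, but a shift of about -0.14 could not have reversed medians of their size. Among single genes chosen after their values were seen, the cell cycle inhibitor Cdkn1b fell from 343 ± 11.0 to 16.3 ± 2.30 CPM, Ccng2 from 254 ± 7.36 to 6.36 ± 1.13 CPM and the Myc antagonist Mxd4 from 189.5 ± 10.9 to 4.19 ± 0.818 CPM, in the same libraries in which the mitotic genes fell.

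The CD4+ T cell libraries held immunoglobulin reads. Ighm stood at 1985 ± 739 and 963 ± 277 CPM, Igkc at 522 ± 289 and 339 ± 107 CPM and Jchain at 219.5 ± 102 and 146 ± 54.9 CPM. The B cell surface gene Cd79a reached 21.7 and 9.61 CPM. Igkc and Jchain did not pass edgeR's test between the groups (adjusted p = 0.258 and 0.256). Both climbed from replicate 1 to 3 in each group, and both were lower in the stimulated library of every number. As many as 106 immunoglobulin V genes had at least 10 reads in every library, and 58 of these were light chain V genes, which argues against germline heavy chain transcription in T cells as the sole source and is consistent with RNA of B-lineage cells. The lowest correlation of V gene usage between same-numbered libraries, over 105 genes that are not independent, was 0.371, so that libraries of 1 number may share the source of these reads. The highest between other numbers was -0.12. As usage was taken as deviation from the group mean, positive values for same numbers push the others down, which is no separate evidence. The pairing by number was the best of the 6 possible ones, the smallest share such a test allows, and T cell receptor V genes showed no such match (-0.091 to 0.021 for same numbers). Whether B-lineage cells survived the culture or only their RNA did is open, and germline Ighm transcription in T cells as a part of the signal is not excluded.

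Interferon-stimulated genes rose in 31 of 32 cases after 4 hours. The choice between TMM and library size shifts all genes by nearly the same amount, -0.14 in the median over all genes. It could thus not have removed a rise of this size. The list median of 2.52 with library size alone follows from that shift and is no separate support. Neither scaling addresses a change in RNA content per cell, which was not measured. The highest of Lyz2, Csf1r, C1qa, C1qb and C1qc in the stimulated libraries was 0.47 CPM, far under 1% of the summed gain of the list, 5108 CPM. By these markers macrophage RNA is argued against. They are a part of the macrophage list, in which Ctss (97.4 to 149 CPM) and Mpeg1 (1.88 to 33.8 CPM) rose. Itgam (3.33 to 0.69 CPM) and Adgre1 (2.05 to 0.734 CPM) of that list fell. The reading thus depends on the choice of markers. Interferon made in the stimulated cultures may account for the rise: reads of the 15 type I interferon genes summed to 84 in the stimulated libraries (16 to 44 each) against 4 in the unstimulated ones, all within 1 library, and Ifng rose from 0.316 to 67.8 CPM. Which type acted stays open, as the interferon gamma receptor gene Ifngr1 fell from 318 ± 52.5 to 25.1 ± 6.56 CPM.

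All 30 G2 and mitosis genes fell, by 0.78 (Ccnb1) to 3.70 (Nusap1) on the log2 scale. The choice between TMM and library size moved the median over all genes by only -0.14. It shifts all genes by nearly the same amount, so it could not have removed a fall of this size. The list median of -1.95 with library size alone follows from that shift and is no separate support. Neither scaling addresses a change in RNA content per cell, which was not measured. Whether cells left the cycle as a whole stays open: in the S phase list 10 of 30 members rose and 13 fell, with a median of -0.10, and with library size alone 8 rose and 17 fell, so members going both ways decide nothing. A lower share of cells in G2 and mitosis, or lower transcription of these genes within cells, stays open and was not tested, since the phase of the cells was not measured.

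Of the 10 ways to divide the 6 libraries into 3 and 3, the real one gave 10320 changed genes and 4741 beyond 2-fold. The highest of the other 9 was 0 in both counts with edgeR, with 7 to 139 genes at an unadjusted p under 0.05, so that 1 of 10 groupings gave as many in each case. For gene lists, 8 of 10 groupings gave at least the 16 lists of the real one, the highest other being 21. Each other grouping mixes the stimulated and unstimulated libraries, which puts the change with stimulation into the spread and leaves part of it between the groups, so these counts are no measure of chance. With 10 groupings no share under 0.05 can be reached. Across genes, which are not independent, the Spearman correlation of the change with exon length was -0.012 and with GC content -0.022.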
